A study of Mus musculus with 6 samples.

How the data were processed

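Messenger RNA of surface IgM-positive B cells, sorted from the bone marrow of C57BL/6 mice at 6 weeks of age, had been enriched by poly(A) selection, made into libraries with an Illumina kit and sequenced by the submitters. There were 6 libraries: 2 of wild-type mice, 2 of mice lacking zinc finger 1 of Ikaros (the ZnF1 mutant) and 2 of mice lacking zinc finger 4 (the ZnF4 mutant). The labels number the libraries of each genotype as replicates and do not say that each came from a different animal, so p-values measure only the spread between these samples. Sex-linked genes show different animals for the 2 libraries of each mutant, and this stays open for wild type. The labels give neither the sex of the mice nor a batch or date, and they do not state whether the libraries kept the strand of the RNA.

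The authors deposited one table of RPKM (reads per kilobase of transcript, scaled to the reads of the library) with 26531 RefSeq transcripts that had values and the length of each transcript. Mapping was to the mouse assembly mm9, and TopHat and bedtools are named in the submitters' processing notes; their versions, and which reads form the total used for scaling, were not given in the sources used here. Values were rounded by the authors to steps of 0.1. RPKM times length in kilobases summed to between 0.775 and 0.833 of that total per library. Read counts could not be recovered from the values: for transcripts shorter than 150 bases, the best read total put at most 41.1% of the values on whole reads. The depth of each library is therefore unknown, and no counting interval or detection floor is given.

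The table held 22098 gene names, of which 3305 had several transcripts; the transcript with the highest mean RPKM stood for its gene. Genes with a mean RPKM of at least 1 over the 6 libraries were tested, which left 10322. Values were used on the scale log2(RPKM + 0.5) without further scaling. The median log2 value of the tested genes lay between 3.62 and 3.68 in the 6 libraries. Fold changes are differences on this scale, so the added 0.5 makes them smaller than the ratio of the means for weakly expressed genes. A table of the assembly GRCm38.p6 was used only for current gene names and for which genes are neighbours. All 6 value columns were used.

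A linear model with 1 coefficient per genotype was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which leaves 3 residual degrees of freedom before moderation. The moderated test is two-sided, and p-values were adjusted over the tested genes by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The comparisons were each mutant against wild type and the mutants against each other. A gene called in only one mutant is said to differ between the mutants only where the direct comparison called it. Because both mutants were compared with the same wild-type libraries, the overlap of their calls was set beside 100 simulations in which no gene changed and the controls were shared.

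In all, 22 gene lists from textbook markers, with 470 members of which 468 were in the table, and the cytosolic ribosomal protein genes were tested with camera of limma at its preset correlation of 0.01, for lists with at least 5 tested members. Adjustment was over 69 tests (23 lists in 3 comparisons). Camera was repeated with a correlation estimated for each list, and fry was run beside it. Single members were also adjusted over the members of their list alone. Members of a list can vary together, so such counts are not independent support for the list. Genes named in the text were taken by a rule: Ikzf1; the 10 largest rises and the 10 largest falls among called genes whose libraries did not overlap and whose higher group had a mean RPKM of at least 3; up to 4 called members of each list, or up to 2 with the smallest p as values where none was called; and the 6 genes with the largest mean change among those called in both mutants. Of the genes that the rule took, 2 are not reported here. Names that are not gene symbols were passed over (2 among the falls in the ZnF4 mutant and 1 among the genes higher in the ZnF1 than in the ZnF4 mutant). The groups, the comparisons, the tests, the lists, this rule and all alternatives but the last 2 given here were chosen before the data were examined. The adjustment over a list alone was not named in that plan.

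The fit was tested on simulated data of 10322 genes with 200 changed genes and the moderated spread of each gene, equal in all genotypes. For changes of 2-, 4- and 8-fold, it recovered 77.6%, 98.5% and 100% in the ZnF1 comparison with 18 false calls, 74.6%, 97.0% and 100% in the ZnF4 comparison with 20, and 79.1%, 91.0% and 100% in the direct comparison with 12. A list shifted by -0.5 was called in each comparison, and 0 other lists were. Simulated genes varied independently, so this does not show how often camera calls lists whose members vary together. The estimated correlation was 0.55 for the interferon response list, the one shifted. The wider spread of the ZnF1 libraries was not simulated either. The SD of their log2 difference was 0.518, against 0.316 in wild type and 0.328 in the ZnF4 mutant.

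The alternatives were another pseudocount, no filter or a stricter one, quantile normalization, median centring, the variance model, a replicate block, fits of only the compared genotypes, each library left out in turn, other thresholds, and the mean over the transcripts of a gene. A term for the sex of the mice, read from Xist and Y-linked genes, and a term for the level of granulocyte and monocyte markers were added after the data had been seen. Only replicate 2 of each mutant was male, so the sex term cannot separate sex from other differences of these libraries. The granulocyte and monocyte level was above wild type in every mutant library and differed most between the ZnF1 libraries. Its term therefore cannot be separated from genotype or from other differences of that pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.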

Results

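RNA levels were measured in IgM-positive bone marrow B cells, that is, B cells that carry their antigen receptor at the surface, from wild-type mice and from mice with either of 2 changes in Ikaros. Ikaros, encoded by Ikzf1, is a zinc finger transcription factor needed for lymphocyte development, and its N-terminal fingers bind DNA. The ZnF1 mutant lacks finger 1 and the ZnF4 mutant lacks finger 4, so the comparisons ask which genes depend on each finger in these B cells. Each genotype had 2 libraries. Values are RPKM, given as mean ± SD with n = 2 unless a library is named, and fold changes are on the log2(RPKM + 0.5) scale.

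Every library had the profile of B cells. Cd79b, a signalling chain of the B cell receptor, lay between 1604 and 2227 RPKM, and Cd3e, a chain of the T cell receptor complex, lay between 0.2 and 0.7. Between 10025 and 10489 gene names per library reached 1 RPKM. The log2 values of the paired libraries correlated across genes with r = 0.984 in wild type, 0.955 in the ZnF1 mutant and 0.981 in the ZnF4 mutant, where genes are not independent replicates. The ZnF1 libraries stood furthest apart, with 460 genes over 2-fold apart against 112 in wild type and 72 in the ZnF4 mutant.

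ZnF1 replicate 2 held more RNA of genes that mark other marrow cells. S100a8, an abundant granulocyte protein gene, was at 1808 RPKM in that library, 416 in ZnF1 replicate 1, 119 and 188 in wild type, and 525 and 428 in the ZnF4 mutant. Hbb-b1, a beta globin gene, was at 354 RPKM in ZnF1 replicate 2 and between 63.6 and 153 in the other libraries, although reads cannot be assigned with certainty among near-identical globin genes. The libraries also differed in sex. Xist, the RNA of the inactive X chromosome, was at 39.6 and 50.7 RPKM in wild type, at 40.0 in ZnF1 replicate 1 and at 66.8 in ZnF4 replicate 1, and it was listed at 0 in replicate 2 of both mutants. Ddx3y, a Y-linked gene, was at 20.4 RPKM in ZnF1 replicate 2 and at 16.6 in ZnF4 replicate 2, and it was listed at 0 in the other 4 libraries.

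Ikzf1 itself was at 177 and 179 RPKM in the wild-type libraries, 201 and 168 in the ZnF1 mutant, and 287 and 244 in the ZnF4 mutant. The log2 fold change was 0.05 in the ZnF1 mutant (SE 0.16, adjusted p = 0.940) and 0.58 in the ZnF4 mutant (SE 0.16, adjusted p = 0.111), and neither passed. The direct comparison gave -0.52 (adjusted p = 0.114). One value per transcript cannot show whether the exon of a finger was missing, so Ikzf1 does not check the genotypes.

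Few genes passed in the ZnF1 mutant, and all 28 called genes changed by at least 1 on the log2 scale. Smaller changes may have been missed with 2 libraries per genotype. Il9r, the receptor for interleukin 9, rose from 6.35 ± 4.31 to 188 ± 3.96 RPKM (log2 fold change 4.94, SE 0.44, adjusted p = 0.0147), and its genomic neighbours Snrnp25, a minor spliceosome protein gene, and Rhbdf1, a rhomboid family gene, rose with it. Snrnp25 went from 21.4 ± 4.03 to 107 ± 0.141 RPKM, and Rhbdf1 from 1.10 ± 0.424 to 19.4 ± 0.0707. The log2 fold change of Il9r was 4.25 without wild-type replicate 1 and 5.63 without wild-type replicate 2, and neither passed (adjusted p = 0.0795 and 0.0573). Sdc1, the syndecan that marks plasma cells, fell from 4.30 ± 1.41 to 0.50 ± 0.141 RPKM, and Bmf, a BH3-only promoter of apoptosis, fell from 45.9 ± 12.1 to 14.4 ± 2.33. H1f0, a linker histone gene, fell from 8.90 ± 1.70 to 1.10 ± 0.141 RPKM.

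The other rises in the ZnF1 mutant were Ppl (log2 fold change 2.32), Serpina3g (2.19), Dkkl1 (2.17), Cd4 (1.97), Eng (1.82), Sema7a (1.24) and Cyp27a1 (1.20). Cd4, the T helper cell co-receptor, went from 0.75 ± 0.212 to 4.35 ± 0.212 RPKM while Cd3e stayed below 1. Serpina3g belongs to a cluster of similar serpin genes among which reads are hard to assign. Further falls were those of the collagen gene Col5a3 (-2.74), Rbpms (-2.34), Emid1 (-2.25), Actr3b (-2.20), the calcium channel gene Cacna1h (-2.0), Myo7a (-1.84) and Inppl1, an inositol phosphatase gene (-1.66). Adjusted p-values of these genes lay between 0.0147 and 0.0429. The strand of the reads is not stated, so overlapping or antisense transcripts cannot be separated from the named genes.

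**Figure D1:**
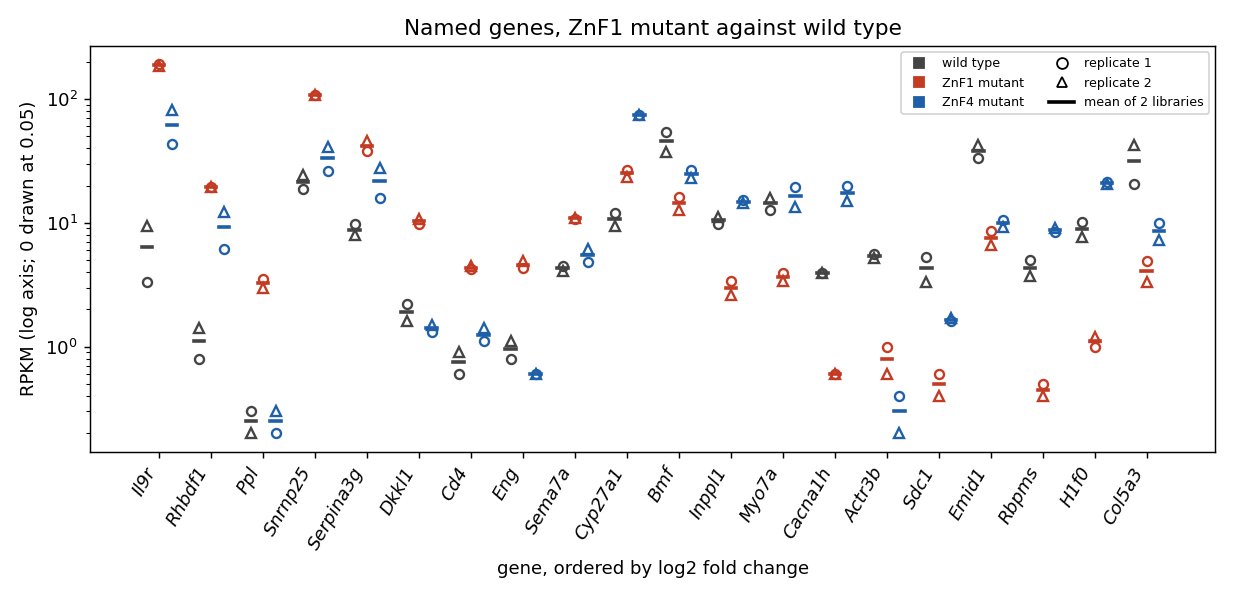
RPKM on a log axis of the 10 genes with a rise and the 10 with the largest fall in the ZnF1 mutant, ordered by log2 fold change. Circles and triangles are replicate 1 and replicate 2, colours are genotypes and bars are means of 2 libraries; Il9r has the largest rise, to 191 and 185 RPKM in the ZnF1 libraries.

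Granulocyte and monocyte markers had the largest list shift in the ZnF1 mutant: all 21 tested members had a positive log2 fold change with a median of 2.27 (adjusted p = 4.75e-12; adjusted p = 0.972 with an estimated correlation), none passed as a single gene, and 18 rose when adjusted over the list alone. The list median per library, relative to the wild-type mean, was 3.60 in ZnF1 replicate 2, 1.01 in ZnF1 replicate 1, 1.41 and 1.47 in the ZnF4 mutant and -0.36 and 0.36 in wild type. Plasma cell genes were lower, with a median of -0.46; 1 of 13 fell (Sdc1), 12 did not pass, and 3 fell when adjusted over the list alone (adjusted p = 0.000126; adjusted p = 0.972 with an estimated correlation). Their library medians were 0.36 and -0.36 in wild-type replicates 1 and 2 and -0.36 and -0.54 in the ZnF1 mutant, so wild-type replicate 1 stood apart. Igj, the antibody J chain gene, chosen after its values were seen, was at 414 RPKM there and at 1.1 in wild-type replicate 2. NK and plasmacytoid dendritic cell markers had a median of 1.29 with 7 of 7 members positive and none passing (adjusted p = 0.00101; adjusted p = 0.972 with an estimated correlation). Their library medians were -0.52 and 0.52 in wild-type replicates 1 and 2 and 0.71 and 1.52 in the ZnF1 mutant.

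A further 5 lists were called higher in the ZnF1 mutant, all with an adjusted p of 0.972 with an estimated correlation, and none of their members passed. They were erythroid and megakaryocyte markers (median 1.22 over 15 members, adjusted p = 0.00181), integrin and cell adhesion genes (0.28 over 17, adjusted p = 0.0021), glycolysis genes (0.29 over 13, adjusted p = 0.0189), cell cycle genes (0.18 over 35, adjusted p = 0.0246) and cytosolic ribosomal proteins (0.20 over 68, adjusted p = 0.0246). Adjusted over the list alone, 1 integrin list member rose and 0 members of the other 4 lists passed. These 5 lists were not called without ZnF1 replicate 2; the erythroid list median was 2.61 in that library and -0.27 in ZnF1 replicate 1. Without wild-type replicate 1 the plasma cell, cell cycle and glycolysis lists were not called, and without wild-type replicate 2 or with quantile normalization the ribosomal list was not. With a term for the level of granulocyte and monocyte markers, none of the 7 ZnF1 lists other than the granulocyte list, whose median is that term, was called in its direction by camera. The erythroid and cell cycle lists were then called lower. That level was above wild type in every mutant library, and within genotypes it differed most between the ZnF1 libraries (1.01 and 3.60). The term thus overlaps with genotype and rests mainly on that pair. These losses and reversals therefore do not show what the lists would be without RNA of other cells. With a term for sex the erythroid, cell cycle, glycolysis and ribosomal lists were not called. The male ZnF1 library is replicate 2, rich in granulocyte and erythroid RNA, so these losses cannot be ascribed to sex. Without a filter on low values the cell cycle and ribosomal lists were not called.

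By limma, 28 of 10322 genes were called in the ZnF1 mutant, 10 higher and 18 lower, and 1232 had an unadjusted p under 0.05. All 28 had libraries that did not overlap between the genotypes, as 41.5% of all tested genes did, where chance gives 33.3%. The count was not stable when 1 library was left out, also where that was a ZnF4 library, which does not enter this comparison. Leaving out a ZnF4 library keeps the fold changes, but fewer samples then estimate the spread, and the widely spread ZnF1 pair weighs more in it. The fit of only the 2 genotypes gave 0 calls (1053 at an unadjusted p under 0.05). With a term for sex the count was 0 (863 at an unadjusted p under 0.05). With a term for the level of granulocyte and monocyte markers it was 8, of which 4 were among the 28.

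In the ZnF4 mutant, Igll1 and Vpreb1, the genes of the surrogate light chain of the pre-B cell receptor, were far higher. Igll1 rose from 9.70 ± 5.66 to 126 ± 6.43 RPKM (log2 fold change 3.75, SE 0.37, adjusted p = 0.00549) and Vpreb1 from 2.85 ± 1.34 to 20.2 ± 7.99 (2.64, adjusted p = 0.0116), while Rag1, a recombinase of antigen receptor genes, fell from 16.1 ± 2.19 to 3.30 ± 1.56 (-2.18, adjusted p = 0.0109). Irf7, a transcription factor of the interferon response, fell from 23.9 ± 4.95 to 6.85 ± 0.354 RPKM (-1.72, adjusted p = 0.00656). Ctnnd1, which encodes the cadherin partner p120 catenin, rose from 1.05 ± 0.0707 to 23.9 ± 1.91 RPKM (3.97, SE 0.18, adjusted p = 0.000571).

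The largest rises in the ZnF4 mutant also included the semaphorin receptor gene Nrp2 (log2 fold change 3.95), the neighbouring membrane protein genes Tmem176b (3.75) and Tmem176a (3.53), Apba1 (3.72), Il9r (3.28), Cyp4f16 (3.26), Rnd3 (3.13) and Cd300c (3.05). Nrp2 was at 0.10 RPKM in both wild-type libraries and at 8.80 ± 0.707 in the mutant. The largest falls also included Actr3b (-2.89), Steap4, a metalloreductase gene (-2.89), Lrrc32 (-2.68), Cox6a2 (-2.49), Il2ra, the alpha chain of the interleukin 2 receptor (-2.36), Oasl1 (-2.20), Reln (-2.13) and Plxdc1 (-1.99). Adjusted p-values of these genes lay between 0.00261 and 0.0353. Without wild-type replicate 1 and without wild-type replicate 2, the log2 fold change was 2.59 and 3.97 for Il9r (adjusted p = 0.0667 and 0.052) and -3.27 and -1.71 for Cox6a2 (adjusted p = 0.0383 and 0.107). For Igll1 it was 3.15 and 4.35, and both passed.

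**Figure D2:**
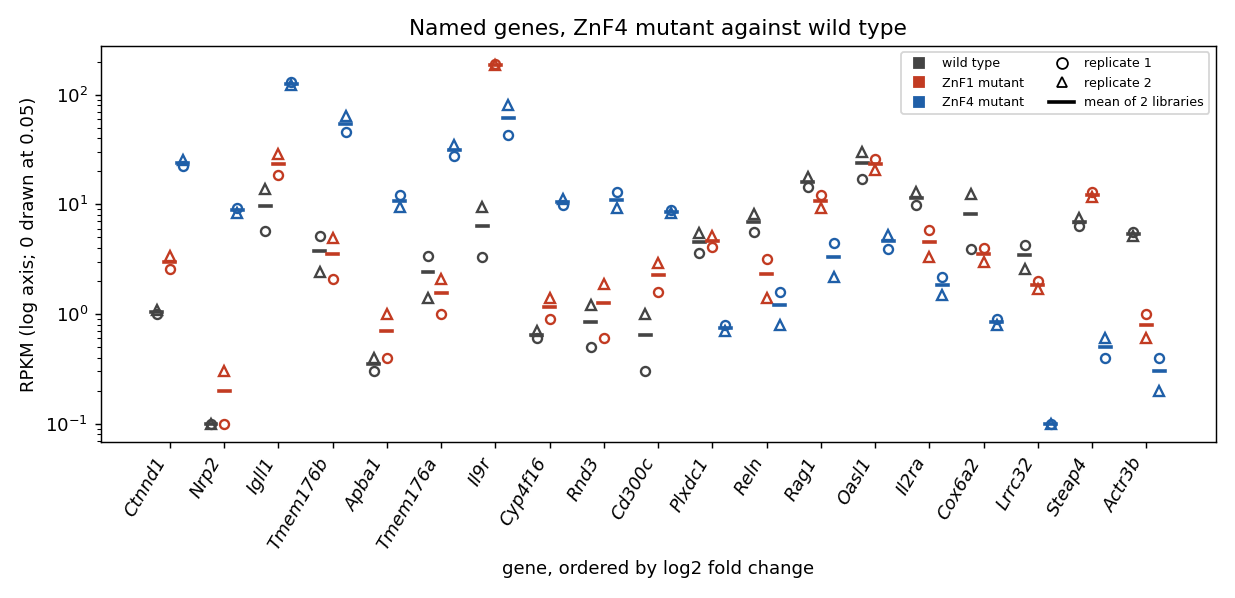
RPKM on a log axis of the 10 genes with the largest rise and 9 of those with the largest fall in the ZnF4 mutant, ordered by log2 fold change. Circles and triangles are replicate 1 and replicate 2, colours are genotypes, bars are means of 2 libraries and values of 0 are drawn at 0.05; Igll1 was at 130 and 121 RPKM in the ZnF4 libraries against 5.7 and 13.7 in wild type.

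Interferon response genes were lower as a list in the ZnF4 mutant, with a median of -0.79; 5 of 29 fell, 24 did not pass, and 19 fell when adjusted over the list alone (adjusted p = 5.31e-11; adjusted p = 0.972 with an estimated correlation). Beside Irf7 and Oasl1, Ifit3 fell by 1.93 and Rtp4 fell by 1.89 on the log2 scale. Cell cycle genes were lower, with a median of -0.49; none of 35 passed, and 7 fell and 1 rose when adjusted over the list alone (adjusted p = 1.06e-06; adjusted p = 0.972 with an estimated correlation). Immediate early and activation genes were lower, with a median of -0.51; 3 of 25 fell, Fosb (-1.48), the phosphatase gene Dusp2 (-1.30) and Egr1 (-0.73), and 5 fell when adjusted over the list alone (adjusted p = 0.0021; adjusted p = 0.972 with an estimated correlation).

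Granulocyte and monocyte markers were higher in the ZnF4 mutant too, with a median of 1.45 over 21 members, none of which passed, also when adjusted over the list alone (adjusted p = 0.00126; adjusted p = 0.972 with an estimated correlation). MHC class II presentation genes had a median of 0.43 over 13 members, none of which passed, and 1 fell when adjusted over the list alone (adjusted p = 0.0218; adjusted p = 0.972 with an estimated correlation). The MHC list was not called without wild-type replicate 2, without ZnF4 replicate 2 or without a filter on low values. Its library medians were 0.13 and -0.13 in wild-type and 0.11 and 0.73 in ZnF4 replicates 1 and 2. With a term for sex, neither of these lists was called in the ZnF4 mutant, and with a term for the level of granulocyte and monocyte markers the immediate early list was not.

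Members of lists that were not called also changed in the ZnF4 mutant. In the pro-B and pre-B cell list, Igll1, Vpreb1 and Kit (2.79), a growth factor receptor gene of progenitors, rose, Rag1 fell and 9 of 13 did not pass; adjusted over the list alone, 3 rose and 5 fell. Among marginal zone and B1 cell genes, the scavenger receptor gene Cd36 rose from 17.8 ± 2.26 to 96.7 ± 22.1 RPKM (2.40), and Dtx1, a Notch target gene (-1.80), and Tm6sf1 (-0.93) fell. Ctnna1, which encodes alpha catenin, rose (1.15) and Vcl, which encodes vinculin, fell (-1.17). The transcription factor genes Foxo1 (-0.80) and Sfpi1, now named Spi1 and encoding PU.1 (-0.79), fell, as did Tnfrsf13c, the receptor gene for the survival factor BAFF, from 426 ± 11 to 240 ± 4.74 RPKM (-0.83). Zbtb20 (1.37), Tlr2 (1.02) and the BH3-only gene Pmaip1 (1.68) rose, and the cell cycle inhibitor gene Cdkn1a fell (-1.63). Dntt, which encodes the terminal transferase that adds bases to antigen receptor genes, had a log2 fold change of -2.88 (adjusted p = 0.0514) and did not pass. It was at 2.1 and 11.1 RPKM in wild-type replicates 1 and 2, and the fold change was -3.95 without the first and -1.80 without the second.

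By limma, 330 of 10322 genes were called in the ZnF4 mutant, 184 higher and 146 lower; 232 had an absolute log2 fold change of at least 1, and 1800 had an unadjusted p under 0.05. All 330 had libraries that did not overlap, as 50.4% of all tested genes did, where chance gives 33.3%. The count was 11 without wild-type replicate 1, 3 without wild-type replicate 2, 591 without ZnF1 replicate 1, 585 without ZnF1 replicate 2, and 0 by limma without ZnF4 replicate 1 (1551 at an unadjusted p under 0.05) or ZnF4 replicate 2 (1219). With a term for sex it was 171, of which 167 were among the 330.

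To ask which genes depended on both fingers, the calls were overlapped, and 11 genes were called in both mutants in the same direction. The 4 higher genes were Il9r, Rhbdf1, Cyp27a1, a sterol hydroxylase gene, and Serpina3g. Il9r was at 61.9 ± 26.7 RPKM in the ZnF4 mutant, and Cyp27a1 went from 10.8 ± 1.91 in wild type to 25.2 ± 2.33 in the ZnF1 and 74.2 ± 0.212 in the ZnF4 mutant. The 7 lower genes were Actr3b, Col5a3, Emid1, Ets2, Akap12, Myl4 and Endou; the last 4 fall outside the rule for named genes and were chosen after their values were seen. H1f0 and Cacna1h were called in opposite directions: H1f0 was at 8.90 ± 1.70 RPKM in wild type, 1.10 ± 0.141 in the ZnF1 and 21 ± 0.707 in the ZnF4 mutant, and Cacna1h at 3.90, 0.60 and 17.5 ± 3.54.

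Independent lists of these sizes would share 0.178 genes called higher, 0.255 called lower and 0.462 called in opposite directions. Simulations with no change and the same controls gave means of 0.04, 0.05 and 0. As no gene changed in them, few shared calls could arise. They therefore do not show how many shared calls the controls add where genes do change. Across genes, the fold changes of the mutants correlated with a Pearson r of 0.36 and a Spearman rho of 0.32, below the simulated means of 0.50 and 0.47 that shared controls alone gave, and their covariance was 0.0700 against 0.0267 in the simulations. Part of the excess of shared genes may come from the shared controls. The 11 became 0 without any single wild-type or ZnF4 library (wild-type replicate 1, wild-type replicate 2, ZnF4 replicate 1, ZnF4 replicate 2), 127 without ZnF1 replicate 1 and 3 without ZnF1 replicate 2. With a term for sex it was 0 as well, where adjusted p-values rose and fold changes moved little. In the ZnF1 mutant, Il9r kept a log2 fold change of 4.72 (adjusted p = 0.0536), Rhbdf1 3.43 (0.0536) and Cyp27a1 1.25 (0.115).

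**Figure D3:**
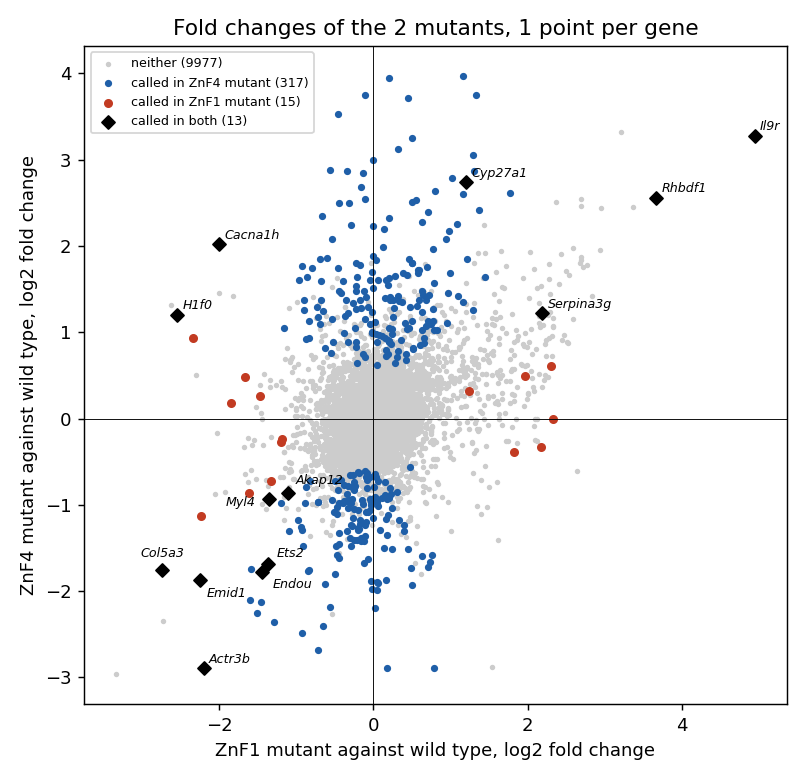
Log2 fold change in the ZnF1 mutant (x axis) against that in the ZnF4 mutant (y axis) for each of 10322 tested genes. Black diamonds are the 13 genes called in both mutants, coloured points are genes called in one of them and grey points are called in neither; H1f0 and Cacna1h lie in the quadrant of opposite signs.

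The direct comparison asks whether losing finger 1 and losing finger 4 had different effects, and single genes differed by large amounts. Dntt was at 15.6 ± 2.97 RPKM in the ZnF1 mutant and 0.25 ± 0.0707 in the ZnF4 mutant, with 2.1 and 11.1 in the wild-type libraries (log2 difference 4.41, SE 0.60, adjusted p = 0.00945). Steap4 was at 12.2 ± 0.919 and 0.50 ± 0.141 RPKM (3.68, adjusted p = 0.00046). Cacna1h (-4.02, adjusted p = 0.000387), Tmem176a (-4.0), the microtubule protein gene Mtap2 (-3.93), Tmem176b (-3.85), H1f0 (-3.75), Nrp2 (-3.74), Wls, which encodes a carrier of Wnt proteins (-3.46), Sema5a (-3.44), Rbpms (-3.28) and Apba1 (-3.26) were lower in the ZnF1 than in the ZnF4 mutant. Cd209d (3.24), Chst10 (3.03), Dkkl1 (2.50), Dusp3 (2.40) and Padi4 (2.35) were higher. Padi4 was at 5.2 RPKM in ZnF1 replicate 1 and 16.9 in ZnF1 replicate 2, the library rich in granulocyte markers, and its log2 difference was 1.55 without ZnF1 replicate 2 and 3.16 without ZnF1 replicate 1.

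Interferon response genes were higher in the ZnF1 than in the ZnF4 mutant, with a median difference of 0.99; 11 of 29 were higher, among them Irf7 (2.43), Ifit3 (2.43), Ifit1 (2.42) and Oasl1 (2.22), 18 did not pass, and 23 were higher when adjusted over the list alone (adjusted p = 4.75e-12; adjusted p = 0.972 with an estimated correlation). Cell cycle genes were higher, with a median of 0.75; 6 of 35 passed, among them Rrm2 (1.22), Top2a (1.09), Nusap1 (1.07) and Birc5 (0.94), and 22 were higher and 1 lower when adjusted over the list alone (adjusted p = 2.52e-09; adjusted p = 0.972 with an estimated correlation). The cell cycle list medians were 0.02 and 0.42 in ZnF1 replicates 1 and 2 and -0.38 and -0.55 in the ZnF4 mutant. Without ZnF1 replicate 2, the library rich in granulocyte and erythroid RNA, the list was still called, but Rrm2 (0.99), Top2a (0.93), Nusap1 (0.92) and Birc5 (0.68) did not pass. Plasma cell genes had a median of -0.42, with Ell2 (-1.25) and Slamf7 (-1.04) lower, 11 of 13 not passing and 4 lower when adjusted over the list alone (adjusted p = 0.00455; adjusted p = 0.972 with an estimated correlation); the list was not called without ZnF4 replicate 1.

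The marker lists of other cells also differed between the mutants. Granulocyte and monocyte markers had a median difference of 0.99, with 21 of 21 members positive and none passing, also when adjusted over the list alone (adjusted p = 0.00693; adjusted p = 0.972 with an estimated correlation). NK and plasmacytoid dendritic cell markers had a median of 1.37, with Bst2 higher (1.29) and Cd300c lower (-1.77) of 7, and 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.972 with an estimated correlation). Neither list was called without ZnF1 replicate 2, the library with the highest granulocyte markers (list median 3.60), or without ZnF4 replicate 2.

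Single members of other lists passed the direct comparison as well. Igll1 (-2.42), Vpreb1 (-1.84), Cd36 (-1.69), Ctnnd1 (-2.81), Ctnna1 (-1.68), Plac8 (-0.80), Pmaip1 (-1.30) and Rbpj, the DNA-binding partner of Notch (-1.01), were lower in the ZnF1 than in the ZnF4 mutant. Rag1 (1.62), Sfpi1 (0.80), Dtx1 (1.31), Tm6sf1 (1.11), Vcl (1.33), Cd4 (1.48), Dusp2 (0.97) and Cdkn1a (1.57) were higher.

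**Figure D4:**
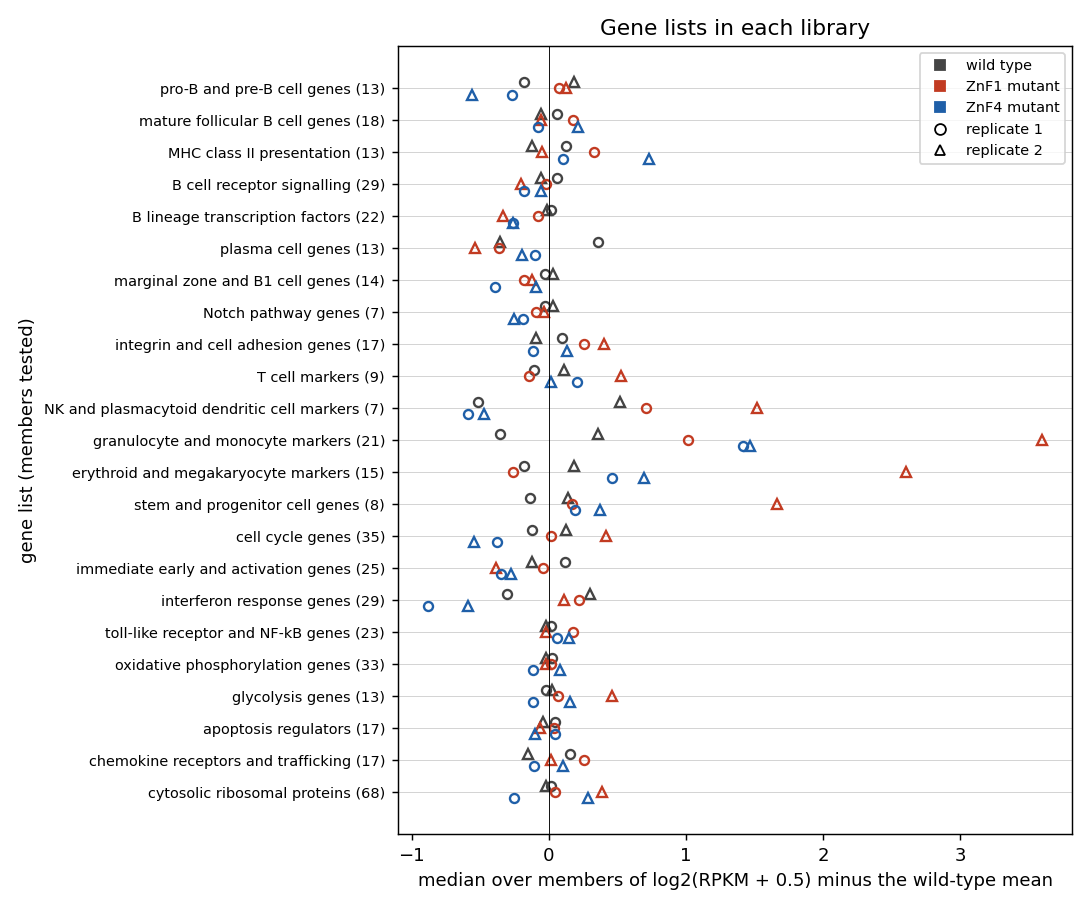
Median over the tested members of each gene list of log2(RPKM + 0.5) minus the wild-type mean (x axis), with the number of members in brackets beside the list name. Each library is 1 point, circles for replicate 1 and triangles for replicate 2, coloured by genotype; granulocyte and monocyte markers reach 3.60 in ZnF1 replicate 2.

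By limma, 493 of 10322 genes were called in the direct comparison, 215 higher and 278 lower in the ZnF1 mutant; 323 had an absolute log2 difference of at least 1, and 2064 had an unadjusted p under 0.05. All 493 had libraries that did not overlap, as 46.8% of all tested genes did, where chance gives 33.3%. The count was 259 without wild-type replicate 1, 259 without wild-type replicate 2, 814 without ZnF1 replicate 1, 352 without ZnF1 replicate 2, 0 by limma without ZnF4 replicate 1 (1689 at an unadjusted p under 0.05) and 2 without ZnF4 replicate 2; with a term for the level of granulocyte and monocyte markers it was 802. Where 1 library was left to a genotype, it was assumed to vary like the other groups.

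The other lists were not called in any comparison. Their smallest adjusted p over the 3 comparisons was 0.0751 for B cell receptor signalling, 0.0783 for B lineage transcription factors, 0.0828 for stem and progenitor cell genes, 0.144 for Notch pathway genes, 0.176 for toll-like receptor and NF-kB genes and 0.238 for chemokine receptors and trafficking. It was 0.413 for marginal zone and B1 cell genes, 0.419 for pro-B and pre-B cell genes, 0.604 for mature follicular B cell genes and for T cell markers, 0.664 for apoptosis regulators and 0.742 for oxidative phosphorylation genes. Median, mean and test differed in sign for the pro-B and pre-B, oxidative phosphorylation and apoptosis lists in the ZnF1 mutant. They also differed for these lists and the plasma cell and NK lists in the ZnF4 mutant, and in the direct comparison for the pro-B and pre-B, B cell receptor, B lineage factor, marginal zone, toll-like receptor and apoptosis lists.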

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

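The tests of other cells' RNA were chosen only after the results were seen, the fit with a sex term was added after the data had been seen, and the direct comparison of the mutants was planned. The results here are the named genes and lists for which that comparison found a difference between the effects of the mutants; groups of 2 libraries are too small for a test of single outlying samples. Values are log2 differences, ZnF1 mutant minus ZnF4 mutant.

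Of the 58 named genes that differed, 2 were called in opposite directions against wild type, Cacna1h (-4.0) and H1f0 (-3.75), and Cyp27a1 (-1.54) was called higher in both mutants. In the ZnF1 mutant alone, 9 were called: Rbpms (-3.28), Inppl1 (-2.14), Myo7a (-2.02), Sema7a (0.93), Cd4 (1.48), Snrnp25 (1.70), Eng (2.21), Ppl (2.32) and Dkkl1 (2.50). Another 17 were called in neither mutant against wild type. Of these, Mtap2 (-3.93), Wls (-3.46), Ell2 (-1.25), Slamf7 (-1.04), Rbpj (-1.01) and Plac8 (-0.80) were lower in the ZnF1 mutant, and Birc5 (0.94), Nusap1 (1.07), Top2a (1.09), Rrm2 (1.22), Bst2 (1.29), Oas3 (1.39), Padi4 (2.35), Ifit1 (2.42), Chst10 (3.03), Cd209d (3.24) and Dntt (4.41) were higher.

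In the ZnF4 mutant alone, 29 were called. Lower in the ZnF1 than in the ZnF4 mutant were Tmem176a (-4.0), Tmem176b (-3.85), Nrp2 (-3.74), Sema5a (-3.44), Apba1 (-3.26), Rnd3 (-2.81), Ctnnd1 (-2.81), Cyp4f16 (-2.75), Igll1 (-2.42), Vpreb1 (-1.84), Cd300c (-1.77), Cd36 (-1.69), Ctnna1 (-1.68) and Pmaip1 (-1.30). Higher were Sfpi1 (0.80), Dusp2 (0.97), Tm6sf1 (1.11), Dtx1 (1.31), Vcl (1.33), Cdkn1a (1.57), Rag1 (1.62), Rtp4 (1.86), Lrrc32 (1.97), Plxdc1 (2.04), Oasl1 (2.22), Dusp3 (2.40), Ifit3 (2.43), Irf7 (2.43) and Steap4 (3.68). By camera, 5 lists differed, given here with their median log2 difference: plasma cell genes (-0.42), NK and plasmacytoid dendritic cell markers (1.37), granulocyte and monocyte markers (0.99), cell cycle genes (0.75) and interferon response genes (0.99). None of these list differences passed with an estimated correlation (adjusted p = 0.972).

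Granulocyte and monocyte markers were higher in the mutants, most in ZnF1 replicate 2, where 21 of 21 members exceeded ZnF1 replicate 1 and S100a8 reached 1808 and S100a9 3135 RPKM; a candidate explanation is RNA of other cells that a sort for IgM should have removed. Genotype alone would give both ZnF1 libraries a like level, and the median log2 difference between them was 2.58 (SD 0.507 over the members), against 0.71 between the wild-type and 0.20 between the ZnF4 libraries, which argues against genotype alone for that excess. Erythroid markers moved with it, by a median of 2.64. In the remaining 3 mutant libraries the lowest list median was 1.01, above the highest wild-type value of 0.36, and there an effect of the genotype and RNA of other cells cannot be told apart, since each genotype has only these libraries and the purity of the sorted cells is not given in the sources used here.

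Igll1 and Vpreb1 were higher in the ZnF4 mutant, by a mean of 3.19 on the log2 scale. RNA from pro-B and pre-B cells might raise the rest of their list too, but the other 11 members had a median of -0.57 (SD 1.43) and Rag1 fell by 2.18. Members already high in wild type, such as Vpreb3 at 581 and 612 RPKM, could hide a small admixture. Among members weakly expressed in wild type, Kit rose by 2.79, while Rag2 (-1.09) and Erg (-0.64) did not rise. Levels in precursor cells of the mutant were not measured. The list therefore cannot decide, and RNA of such cells, or of a subset with Igll1, Vpreb1 and Kit, is left open. The sex of the animals was tested with a term in the fit: Igll1 kept a log2 fold change of 3.62 with an adjusted p of 0.0217, and Vpreb1 had 2.96 with 0.0173, so sex does not account for the rise. Over the alternatives the adjusted p of Igll1 lay between 0.00192 and 0.123, and it was above 0.05 without a filter (0.0504), without ZnF4 replicate 1 (0.123) and without ZnF4 replicate 2 (0.121), while its fold change was 3.75, 3.70 and 3.80 there. An effect of the ZnF4 genotype on these genes may remain, as a hypothesis found and tested on the same data.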

How the results depend on the processing

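The sex term and the granulocyte score term were chosen after seeing the data. With changes of pseudocount, median centring, variance model or transcript choice, every count, the correlation (0.36) and the number of lists called (18) stayed within 1.5 times or within their spread. The settings below moved a result. For fits without a library or with only 2 genotypes, fewer samples estimate the spread, and which samples remain matters too. The ZnF1 pair had the widest spread (SD of the log2 difference 0.518, against 0.316 in wild type and 0.328 in the ZnF4 mutant). The ZnF4 count rose to 594 in the fit without the ZnF1 libraries, which fewer samples alone would not give. Elsewhere the cause was not tested unless given. Counts are in the order ZnF1 mutant, ZnF4 mutant, direct comparison and genes shared by the mutants, reported as 28, 330, 493 and 11. Depth is unknown, so it sets no limit that can be stated.

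Without a filter (14585 genes tested, with more weakly expressed ones) they were 0, 189, 309 and 0, and limma gave 1596 ZnF1 genes at an unadjusted p under 0.05. With a mean of at least 5 RPKM (7722 tested) the ZnF4 count was 212, of which 202 were among the 330. Quantile normalization gave 13 ZnF1 and 5 shared genes. Fits of only 2 genotypes gave 0 (1053 unadjusted), 594, 249 and 0. An adjusted p under 0.1 gave 74, 605, 918 and 28 by construction, and a log2 change of at least 1 gave 323 in the direct comparison. With an estimated correlation 0 lists were called and by fry for a shift in one direction 0, where the smallest adjusted p was 0.972 and 0.505. For changes in either direction fry passed 33 of 69 tests (smallest adjusted p = 0.000803). The sex term gave 0 (863 unadjusted), 171 and 0 shared, with a correlation of 0.22. The granulocyte score term gave 8 ZnF1, 802 direct and 6 shared genes.

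Leaving out each library in turn gave 0 to 512 ZnF1, 0 to 591 ZnF4, 0 to 814 direct and 0 to 127 shared genes, and a correlation of 0.23 to 0.44. A replicate block gave 27, 327, 529 and 11, with 21 of the 28, 290 of the 330 and 460 of the 493 still called. Correlations of replicate differences between genotypes were 0.28, -0.03 and 0.21. They do not decide whether libraries with the same replicate number belong together. Of 193 fold changes of named genes, no planned setting other than leave-outs reversed any. Leave-outs put Epor in the direct comparison between -0.29 (without ZnF1 replicate 2) and 2.10. With the granulocyte score term, Car1 (-0.41), Gata1 (-0.57), Birc5 (-0.045) and Ccr2 (-0.011) reversed in the ZnF1 mutant and Hemgn (-0.68) in the ZnF4 mutant; none of them had been called. Calls of named genes were lost most often without ZnF4 replicate 1 (108) or 2 (106), without wild-type replicate 1 (61) or 2 (67) and without a filter (67).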

Other observations

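The test of where called genes lie and the tests of the Il9r neighbourhood were chosen only after the results were seen. Some members of lists that did not pass are given here as values. In the ZnF1 mutant the pro-B and pre-B list (median 0.11, adjusted p = 0.745) and the mature follicular list (0.07, adjusted p = 0.742) were not called. Dntt and Erg of the first were higher there and Cd38, S1pr1 and Ccr7 of the second lower, and none of these 5 passed. Cd93, a marker of immature B cells, was at 41.9 ± 0.636 RPKM in wild type, 21.6 ± 1.34 in the ZnF1 and 28.0 ± 8.34 in the ZnF4 mutant (n = 2 each; adjusted p = 0.124 in the ZnF1 mutant). Cr2, the complement receptor of mature B cells, was at 23.9 ± 1.13, 43.1 ± 1.41 and 31.9 ± 9.48 RPKM (adjusted p = 0.163). Ebf1, a B lineage transcription factor gene, was at 101 ± 10.2, 66.5 ± 9.69 and 74.7 ± 5.66 RPKM (adjusted p = 0.188), and Nfkb2 at 86.0 ± 13.1, 152 ± 1.48 and 129 ± 10.3 (adjusted p = 0.0977).

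Egr1, an immediate early gene, was at 36.0 ± 3.54 RPKM in wild type and at 20.2 ± 1.91 in the ZnF1 mutant (adjusted p = 0.0819), near the 21.6 ± 1.91 of the ZnF4 mutant, where it passed. Tlr2 was at 7.50 ± 0.141, 13.8 ± 2.26 and 15.8 ± 1.41 RPKM (adjusted p = 0.1 in the ZnF1 mutant). Ctnnd1 had a log2 fold change of 1.17 in the ZnF1 mutant (adjusted p = 0.0687). S1pr3 was at 4.6 ± 0.283 RPKM in wild type, 1.95 ± 0.778 in the ZnF1 and 2.45 ± 0.354 in the ZnF4 mutant (adjusted p = 0.171).

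Il9r, Snrnp25 and Rhbdf1, which rose in the ZnF1 mutant, are neighbours among the tested genes and lie on the chromosome of Ikzf1. Of 100000 random sets of 28 tested genes, a share of 0.00015 held 3 in a row, but the run had been seen before it was tested, so chance placement stays open. RNA from erythroid cells is a source to weigh, and it would raise them in ZnF1 replicate 2, but their median log2 difference between the ZnF1 libraries was -0.0072, against 2.64 (SD 0.654) for 15 erythroid markers. Passenger DNA linked to the altered gene may account for them: 0 of the 52 tested genes between Ikzf1 and Il9r were called in the ZnF1 mutant and 2 in the ZnF4 mutant, Emid1 on the other side of Ikzf1 was called lower in both, and this cannot be told apart from a regulatory effect on the neighbourhood, because it needs the genotypes of the region.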
